A study of Homo sapiens with 6 samples.

How the data were processed

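Gene expression was measured on 6 Illumina BeadChip arrays with RNA labelled as SNU761, an established hepatocellular carcinoma cell line. Per the labels, 3 arrays came from cells given the vehicle DMSO and 3 from cells given sorafenib at 3 mM, each for 24 h; the dose is printed as the labels give it, but a millimolar dose is far above those usual in culture, so the unit is uncertain. The labels name other cell lines too, but give SNU761 for all 6 arrays. RNA was made into biotin-labelled cRNA with a kit for these arrays. The labels do not say whether the replicates of a group were separate cultures, so that the p-values measure the spread between the samples as deposited.

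The authors deposited signal intensities, described as non-normalized, in 1 table per group. Each table held 34690 gene symbols with 1 value per symbol and array, so that the probes of a gene had been combined by the authors in a way that is not stated. Per the file headers, each intensity was followed by a detection p-value, the chance that background gives as high a signal. On all 6 arrays the detection p-values of 27247 symbols were whole multiples of 1/770 (tolerance 0.001), as for a single probe set against 770 negative controls. Those of the remaining symbols were not whole multiples on every array. The authors also deposited a table of log2 values. Its 3 control columns equalled quantile-normalized log2 signals without background correction (largest difference 5e-07). Its 3 sorafenib columns were filled for 59 symbols only, and these values belonged to other symbols: 0 of 59 matched the signal of the symbol on their own line within 0.001. That table was therefore not used for any comparison.

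Both signal tables were joined by symbol and normalized together with limma 3.58.1 in R 4.3.3. Background was corrected with the neqc method (offset 16). Its background distribution was taken from the detection p-values of the 27247 symbols that behaved as single probes. This restriction was chosen after the values were seen, since p-values combined over probes would not place a symbol on the scale of the negative controls. The plan set no such restriction, so the estimate from all symbols, given as an alternative, is closer to it. The estimated background had a mean of 112 to 139 and an SD of 20.1 to 31.8 intensity units per array. Arrays were then quantile-normalized and brought to log2. Symbols with a detection p under 0.05 on at least 3 of the 6 arrays were tested, which left 14641. Some bright symbols did not pass this filter. Their detection p-values may have been combined over probes and so not be comparable with those of single probes, which was not tested. Symbols were matched to current gene names where possible: 17761 were current, 3305 were an older name of 1 gene, and 13624 were unmatched. Probe sequences and positions were not used here, so no coordinates are given.

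The groups were compared with limma (linear model, empirical Bayes, two-sided moderated test), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The planned fit, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The planned fit held the group alone. Because the correlations of the arrays' deviations from their group mean, between arrays of the same number, were 0.904, 0.791 and 0.926, the numbers were taken to pair the samples, and a fit with the replicate number as a block is given beside the planned one. A further paired fit, with a variance trend and robust estimation, is called the paired trended fit. It was chosen after the other fits had been seen to call 0 genes, so its calls are exploratory.

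In all, 33 gene lists were written from general knowledge, and 32 had at least 3 tested members. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera was also run with a correlation estimated from the data, and fry was run as a self-contained test. Members past the threshold were counted over all genes tested and adjusted over the list alone. A pair is the sorafenib and the control array of the same number, and a value given with ± is the mean and SD of the log2 difference over the 3 pairs.

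The planned rule named the 10 largest changes in each direction among genes past the threshold with groups fully apart, every tested member of the protein disulfide isomerase list, and up to 3 changed members of each other list. As the planned fit called 0 genes, it named only the 15 protein disulfide isomerase members. The same rule was then applied to the paired trended fit, asking for the same direction in every pair in place of groups fully apart, which named 34 further genes, not all of which are given in the text. Any other gene named was chosen after its values were seen.

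The pipeline was tested on simulated data with 14641 genes, of which 100 were changed 2-fold and 100 were changed 4-fold. The fit without a block called 0% of both. The blocked fit called 4% and 59% with 1 false call, and the paired trended fit called 8% and 59% with 0 false calls. The simulated errors were drawn once and independently for each gene and array. They therefore cannot show how many false calls arise where genes are correlated, as they may be in these data. Alternatives changed the background correction, the offset, the scaling, the detection filter, the variance model, array weights, the pairing, the set test and the arrays included. Chosen after the data were seen were the paired trended fit with its own alternatives, the set tests with the replicate block, and the fits without both arrays numbered 3. The background estimate from all symbols was added as an alternative after the data were seen, although it is closer to the plan than the main estimate. Not run were the deposited log2 table, for the reason above, the mean of a gene's probes and a value per probe, since the tables hold 1 value per symbol, and a slide or scan block, since the files name none.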

Results

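Expression was profiled in cells labelled as SNU761, a cell line from hepatocellular carcinoma, after 24 h with sorafenib or with the vehicle DMSO alone. Sorafenib is a multikinase inhibitor whose targets include RAF kinases and the receptors of VEGF and PDGF. There were 3 arrays per group, numbered 1 to 3 in each, and the dose was 3 mM as the labels write it, a unit that is uncertain. The series title sets sorafenib beside inhibition of protein disulfide isomerase (PDI), an enzyme family that forms and rearranges disulfide bonds in the endoplasmic reticulum (ER). The comparison therefore asked which genes differed in level after sorafenib, with the PDI family, ER chaperones, ATF4 targets and MAPK/ERK output genes as the main groups. Each array gave a signal for 34690 gene symbols, of which 13195 to 15227 per array were detected above background. The median signal per array was 134 to 171 intensity units, and 14641 symbols were tested. The number of arrays limits the precision.

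Arrays of the same number were more alike than arrays of the same group. Across genes, which are not independent replicates, Pearson's r between the control and the sorafenib array of a number was 0.984, 0.966 and 0.978. Arrays numbered 1 and 2 correlated at 0.932 to 0.959 with each other, and arrays numbered 3 at only 0.793 to 0.833 with the other 4. Replicate number held 88.1% of the sum of squares over tested genes, and treatment held 6.94%. On both arrays numbered 3, transcripts of the liver-secreted proteins APOA2 (mean log2 of 5.39 against 15.09 on the other 4 arrays), APOA1 (5.64 against 14.06) and TTR (5.33 against 13.49) were near background. The oncofetal protein GPC3 was at 4.84 against 14.06. Conversely, RAC2, a GTPase of blood cells, was at 14.27 against 5.27, and the basement membrane collagen COL4A1 was at 14.03 against 5.36. These genes were chosen after their values were seen. As both arrays numbered 3 expressed other genes, a mean or SD over the 3 pairs may not describe replicates of the same cells.

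**Figure D1:**
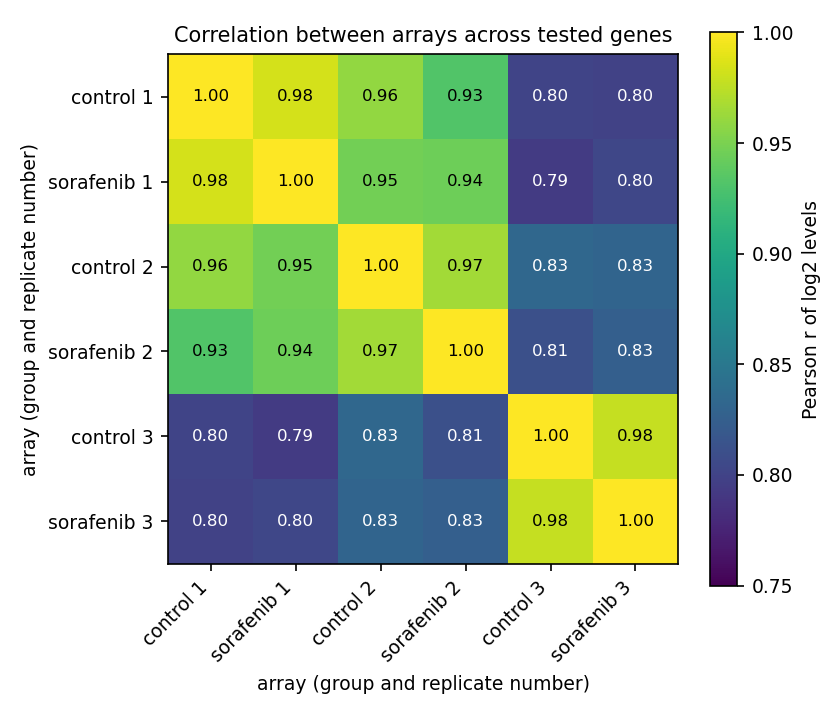
Pearson's r of log2 signal across tested genes for each pair of the 6 arrays (control and sorafenib, numbered 1 to 3). Arrays of the same number have r of 0.966 to 0.984, while the arrays numbered 3 have r of 0.793 to 0.833 with the other 4.

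After sorafenib, targets of the stress transcription factor ATF4 and metallothioneins shifted up, and genes of cholesterol synthesis, heat shock proteins and MAPK/ERK output genes shifted down, in camera with a preset correlation; with an estimated correlation 0 of 32 lists passed, and 4 had an unadjusted p under 0.05. With the preset correlation, limma's camera passed 10 of the 32 lists, 4 upward and 6 downward; fry also called 0 lists. Camera with the preset correlation and the replicate block passed 11 lists, the same 10 and the list of G1/S and DNA replication. Their adjusted p ran from 3.13e-08 for ATF4 targets to 0.0147 for autophagy and lysosome genes. With the block, camera with an estimated correlation and directional fry again called 0. Fry's mixed test, which asks only whether members change in either direction, then passed 14 lists. Gene by gene, the planned limma fit called 0 of 14641 genes, with 310 at an unadjusted p under 0.05. The fit with the replicate number as a block also called 0, with 2777 at an unadjusted p under 0.05 and a lowest adjusted p of 0.101. The paired trended fit, chosen after these counts were seen, called 141 genes, 74 higher and 67 lower, and 106 of them differed at least 2-fold. That count was 0 when the background was estimated from all symbols, 49 without pair 1, 1 without pair 2 and 1375 without pair 3. The plan did not restrict the background estimate to symbols that behaved as single probes, so the estimate from all symbols is closer to it. Single genes are said below to have risen or fallen by the paired trended fit, and their adjusted p is from it. List p-values are from the planned fit, which ignores the pairing, unless another setting is named. Counts of changed list members are from the paired trended fit too, since in the planned fit 0 members of any list passed, over all genes or adjusted over the list alone. Fits without 1 array hold no block. The partner of that array then stays unmatched, so that differences between replicate numbers enter the sorafenib difference.

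The ATF4 list, genes of amino acid supply and stress signalling, had 35 tested members with a median log2 difference of 0.56. The medians of pairs 1, 2 and 3 were 0.29, 0.22 and 1.10, and 23 members were higher and 0 lower in all 3 pairs. The list rose (camera adjusted p = 1.77e-09; adjusted p = 0.297 with an estimated correlation). Over all genes 6 members rose, and 19 changed when adjusted over the list alone. DDIT3, the transcription factor CHOP, rose by 2.71 ± 0.83 (6.52-fold; SD, n = 3 pairs; adjusted p = 0.0202). NUPR1, a stress-induced chromatin protein, rose by 2.18 ± 0.53, and the secreted cytokine GDF15 rose by 1.96 ± 0.89. TRIB3 differed by 0.54 and ATF4 itself by 0.51, and neither passed the threshold. CHAC1 went both ways, at −1.11, −0.84 and 2.71 in pairs 1, 2 and 3. Without control replicate 3 the list median was 0.37, and without both arrays numbered 3 it was 0.31, with the list still past the threshold.

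The PDI family showed no shift past the threshold. Its 15 tested members had a median of −0.17, with pair medians of 0.04, −0.21 and −0.21, and 3 members were higher and 5 lower in all 3 pairs (camera adjusted p = 0.53). The median was −0.26 without control replicate 3, −0.07 without control replicate 2, −0.06 without sorafenib replicate 2 and 0.07 without sorafenib replicate 3; it was 0.0049 without a detection filter and −0.01 with the background estimated from all symbols. With limma, 0 members passed over all genes in the planned, blocked or paired trended fit, and 0 adjusted over the list alone. TXNDC5 differed by −0.52 ± 0.10 (adjusted p = 0.122) and TXNDC11 by 0.43 ± 0.16 (adjusted p = 0.224). P4HB, the archetypal PDI, differed by 0.0049 ± 0.10, a sign that turned with median scaling (−0.03) and without control replicate 2 (−0.07), control replicate 3 (−0.04) or sorafenib replicate 1 (−0.17). The other members were TMX3 at −0.46 ± 0.42, DNAJC10 at −0.33 ± 0.33, PDIA5 at −0.26 ± 0.30, ERP44 at −0.25 ± 0.13, TMX2 (as TXNDC14) at −0.24 ± 0.14, PDIA4 at −0.19 ± 0.05 and PDIA6 at −0.17 ± 0.24. Above 0 were TMX4 at 0.10 ± 0.07, TXNDC12 at 0.13 ± 0.31, ERP27 at 0.19 ± 0.66, AGR2 at 0.22 ± 0.78 and ERP29 at 0.25 ± 0.24. A further 6 members did not pass the detection filter and were not tested. Among them TMX1 had a bright signal (log2 of 10.80 in control and 10.31 in sorafenib) and was lower in all 3 pairs, at −0.49 ± 0.14. PDIA3 and the other untested members were near background, with differences of −0.01 to 0.11. A signal near background does not show that the RNA was absent. The 29 ER chaperones and genes of the unfolded protein response had a median of −0.05 (camera adjusted p = 0.973), with 4 higher and 11 lower in all pairs. Their median was −0.16 without sorafenib replicate 1, −0.09 without control replicate 2, −0.11 without control replicate 3, −0.08 without sorafenib replicate 3, 0.07 without control replicate 1, 0.05 without sorafenib replicate 2 and −0.11 without both arrays numbered 3, and fry's mixed test passed with the replicate block (adjusted p = 0.0216). Of them HERPUD1, a factor of ER-associated degradation, rose by 1.24 ± 0.53, the only call over all genes, and 4 members passed when adjusted over the list alone. HSPA5, the main ER chaperone, went both ways, at 0.20, −0.80 and 1.43 in pairs 1, 2 and 3. The ER oxidoreductase partners had a median of −0.20 (camera adjusted p = 0.297).

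**Figure D2:**
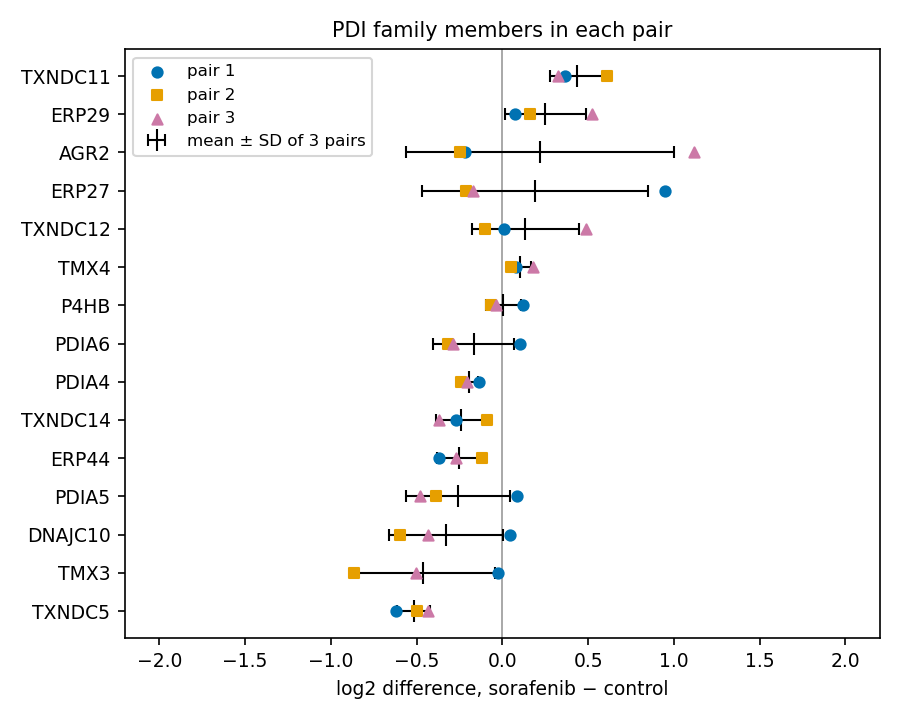
Log2 difference, sorafenib minus control, of the 15 tested PDI family members; symbols are the 3 pairs and bars their mean with SD. None passed the threshold; TXNDC5 lies at −0.52 and P4HB near 0, where its sign turned with median scaling and without control replicate 2, control replicate 3 or sorafenib replicate 1.

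MAPK/ERK output genes, which follow signalling below RAF, had a median of −0.60 over 21 members, with pair medians of −0.72, −0.64 and −0.06. In all 3 pairs 11 members were lower and 1 was higher, and the list fell (camera adjusted p = 0.00644; adjusted p = 0.378 with an estimated correlation). Over all genes 2 members fell, and 10 changed when adjusted over the list alone. The phosphatase DUSP6 fell by 1.55 ± 0.56 (adjusted p = 0.0386) and the feedback inhibitor SPRY2 fell by 0.78 ± 0.17 (adjusted p = 0.0409). DUSP6 was detected on 2 of 3 control and 2 of 3 sorafenib arrays. EGR1 differed by −1.35 and CCND1 by −0.64, while PHLDA1 differed by 1.20, each short of the threshold. The list median was −0.25 without sorafenib replicate 1 (adjusted p = 0.178), −0.16 without sorafenib replicate 2 (adjusted p = 0.106), −0.25 without a detection filter (30 members; adjusted p = 0.0123) and −0.24 with the background estimated from all symbols.

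Genes of cholesterol synthesis and uptake under SREBP2 had a median of −0.51 over 25 members, with pair medians of −0.51, −0.27 and −0.68. In all pairs 19 were lower and 2 higher, and the list fell (camera adjusted p = 2.4e-07; adjusted p = 0.0954 with an estimated correlation). Over all genes 3 members fell, and 15 changed when adjusted over the list alone. HMGCS1, an early enzyme of the pathway, fell by 1.16 ± 0.47 (adjusted p = 0.0384), and squalene epoxidase SQLE fell by 0.87 ± 0.36 (adjusted p = 0.0469). Without sorafenib replicate 3 the list median was −0.33. The 11 genes of fatty acid synthesis had a median of −0.26, with 7 lower and 0 higher in all pairs, and fell as a list (camera adjusted p = 0.00306; adjusted p = 0.229 with an estimated correlation). None passed over all genes and 4 when adjusted over the list alone; without control replicate 3 the list median was −0.45 and the adjusted p was 0.0589.

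Cytosolic heat shock proteins had a median of −0.46 over 20 members, with pair medians of −0.56, −0.48 and −0.35, and 12 were lower and 0 higher in all pairs. The list fell (camera adjusted p = 1.1e-05; adjusted p = 0.0954 with an estimated correlation). Over all genes 5 members fell, and 11 changed when adjusted over the list alone. HSPA1B fell by 1.37 ± 0.03 (adjusted p = 0.0202) and HSPA1A fell by 1.34 ± 0.50, but these inducible HSP70 genes are nearly identical and their signals may not be separate. The cochaperone DNAJA1 fell by 0.93 ± 0.11. The 8 metallothioneins, small metal-binding proteins, had a median of 1.28, with pair medians of 1.37, 2.18 and 0.21, and 6 were higher and 0 lower in all pairs. The list rose (camera adjusted p = 0.00103; adjusted p = 0.361 with an estimated correlation). None passed over all genes, MT1F being nearest at 1.44 (adjusted p = 0.0506), and 8 passed when adjusted over the list alone. The metallothionein median was 0.50 without sorafenib replicate 2 (adjusted p = 0.106) and 2.26 without sorafenib replicate 3.

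Genes of G2/M and mitosis had a median of 0.39 over 35 members, with pair medians of −0.15, 0.14 and 1.23, and 7 were higher and 0 lower in all pairs. The list passed upward (camera adjusted p = 0.00644; adjusted p = 0.907 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Without both arrays numbered 3 the median was −0.01 and the test turned downward (adjusted p = 0.322), as it did without control replicate 3 alone, at −0.18 (adjusted p = 0.0635). It stayed upward without sorafenib replicate 3, at 0.56 (adjusted p = 0.0956), and without sorafenib replicate 2, at 0.26 (adjusted p = 0.106), while the median was 0.72 without control replicate 1 and 0.68 without control replicate 2. The median was 0.26 with the background estimated from all symbols. The 31 genes of G1/S and DNA replication had a median of −0.33, with pair medians of −0.85, −0.33 and 0.03, and 12 were lower and 0 higher in all pairs. They did not pass in the planned fit (camera adjusted p = 0.053; adjusted p = 0.978 with an estimated correlation) and fell with the replicate block (adjusted p = 0.000751; adjusted p = 0.928 with the block and an estimated correlation), with 0 members past the threshold over all genes and 3 adjusted over the list alone. They also passed without background correction (adjusted p = 0.0417), with an offset of 50 (0.0454), with median scaling (0.0482), without a detection filter (0.0125), with trend and robust estimation (0.0485), with array weights (0.000211) and with the background estimated from all symbols (0.0124). Without both arrays numbered 3 their median was −0.52 (adjusted p = 5.75e-08). Without control replicate 3 their median was −1.02 (adjusted p = 5.8e-11), and without sorafenib replicate 2 it was −0.71 (adjusted p = 3.67e-05); without control replicate 1, control replicate 2 or sorafenib replicate 3 it was 0.04, 0.07 and 0.17.

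Genes of glycolysis had a median of −0.49 over 19 members, with 10 lower and 1 higher in all pairs, and fell as a list (camera adjusted p = 0.0167; adjusted p = 0.378 with an estimated correlation). Over all genes 1 member passed and 6 when adjusted over the list alone. PFKFB3, which makes an activator of glycolysis, fell by 1.15 ± 0.02 (adjusted p = 0.0384). The list median was −0.10 without control replicate 3 (adjusted p = 0.285), −0.13 without sorafenib replicate 1 (adjusted p = 0.264) and −0.32 without sorafenib replicate 3 (adjusted p = 0.0731). It was −0.32 without both arrays numbered 3 (adjusted p = 0.0563, and 0.0438 with the replicate block), −0.17 without a detection filter (24 members; adjusted p = 0.0372) and −0.29 with the background estimated from all symbols. Autophagy and lysosome genes had a median of 0.24 over 22 members, with 9 higher and 1 lower in all pairs, and rose as a list (camera adjusted p = 0.0166; adjusted p = 0.461 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Their median was 0.12 without control replicate 1 (adjusted p = 0.142), 0.01 without control replicate 2 (adjusted p = 0.514), 0.11 without sorafenib replicate 3 (adjusted p = 0.511) and 0.46 without control replicate 3; with the background estimated from all symbols it was 0.13. Markers of fibroblasts and stellate cells, a check on what else the samples held, had a median of −0.64 over 7 members, with 4 lower and 0 higher in all pairs. They fell as a list (camera adjusted p = 0.0488; adjusted p = 0.378 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Their median was 0.44 without control replicate 3 (adjusted p = 0.663), −0.29 without sorafenib replicate 1 (adjusted p = 0.053), 0.02 without sorafenib replicate 2 (adjusted p = 0.425) and −1.22 without sorafenib replicate 3. It was −0.41 without background correction, −0.26 without a detection filter (14 members; adjusted p = 0.239) and −0.08 with the background estimated from all symbols.

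**Figure D3:**
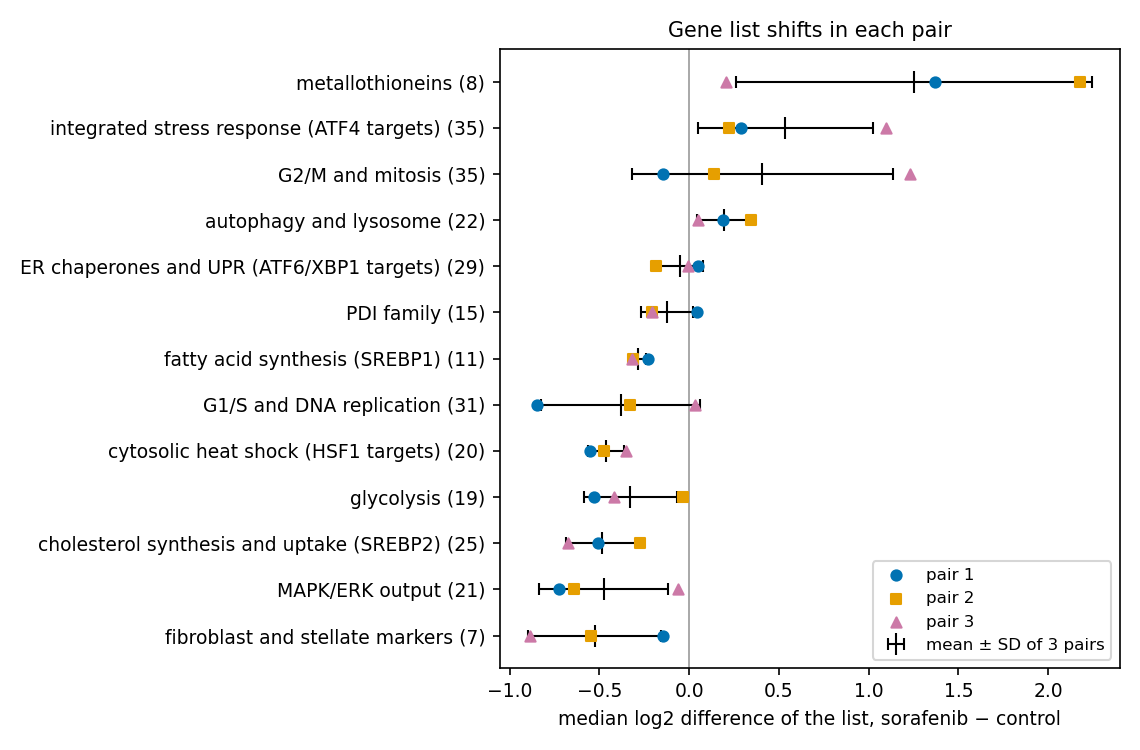
Median log2 difference, sorafenib minus control, of the lists past the threshold and of the PDI, ER chaperone and G1/S lists (tested members in parentheses); symbols are the medians of the 3 pairs, and bars their mean with SD. The ATF4 list lies at 0.29, 0.22 and 1.10 in pairs 1, 2 and 3, and the cholesterol list at −0.51, −0.27 and −0.68.

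The remaining lists did not pass the threshold in the planned fit. Their medians were 0.09 for ribosomal proteins (adjusted p = 0.159), −0.20 for hypoxia targets (0.42), 0.07 for NF-kB targets (0.547), −0.08 for NRF2 targets (0.635) and 0.05 for interferon-induced genes (0.77). They were −0.09 for hepatocyte transcription factors (0.771), −0.06 for hepatocyte secreted proteins (0.887), 0.05 for the BCL2 family (0.864), −0.0049 for p53 targets (0.864), 0.06 for ferroptosis genes (0.973) and −0.08 for epithelial to mesenchymal transition (0.887). Oxidative phosphorylation, fatty acid oxidation and ribosome biogenesis lay near 0, at adjusted p of 0.864, 0.864 and 0.982. As checks, short-lived RNAs were at 0.18 (0.442), long-lived RNAs at −0.12 (0.264), leukocyte markers at −0.19 (0.982) and cholangiocyte markers at 0.12 (0.982); the endothelial list had 1 tested member and was not tested. Without control replicate 3 the hepatocyte secreted list had a median of −1.14 (adjusted p = 0.0182) and NF-kB targets one of 0.61 (adjusted p = 0.00518). Without sorafenib replicate 1 these were −0.90 (adjusted p = 0.0461) and 0.59 (adjusted p = 0.0107), and short-lived RNAs were at 0.62 (adjusted p = 0.0062). The hepatocyte secreted list turned to 0.95 without sorafenib replicate 3 (adjusted p = 0.108), 0.50 without control replicate 1 and 0.30 without control replicate 2. In each of these fits the partner of the array left out stayed unmatched, without a block. The 30 genes of this list with a signal had a median difference of −2.63 between the arrays numbered 3 and the others. These swings therefore hold differences between replicate numbers and cannot be read as shifts with sorafenib alone. Ribosomal proteins passed at 0.14 without control replicate 1 (adjusted p = 0.0394), at 0.11 with median scaling (adjusted p = 0.0262), at 0.10 with the background estimated from all symbols (adjusted p = 0.0252) and in the paired trended fit (adjusted p = 0.00121), as long-lived RNAs did in that last fit (adjusted p = 0.0473). In the planned fit of all arrays, ribosomal proteins had an adjusted p = 0.907 with an estimated correlation (0.928 with the block as well) and long-lived RNAs 0.505 (0.889); hepatocyte secreted proteins had 0.986, and NF-kB targets and short-lived RNAs 0.978 each. Adjusted over the list alone, the paired trended fit called 10 of 20 hypoxia targets, 10 of 22 short-lived RNAs and 6 of 16 NF-kB targets, and fewer in the other remaining lists. Such counts are thus not particular to lists that passed. Over the alternatives, the hypoxia median ranged from −0.54 to 0.07 and the cholangiocyte median from −0.53 to 0.19. In 7 lists, among them the ER chaperones, the median, the mean and the test differed in sign. Besides GADD45A and IRF1, given with the largest changes, single members of these lists that changed were ANKRD37, which fell by 1.39 ± 0.03 (−0.10 with the background estimated from all symbols), SOX4, which fell by 1.15 ± 0.30, CCL20, which fell by 0.88 ± 0.40, and the peroxiredoxin PRDX1, which fell by 0.54 ± 0.22.

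The largest rise was in PIM1, a serine/threonine kinase gene induced by STAT signalling, by 2.80 ± 0.73 (6.98-fold; adjusted p = 0.0202). The growth arrest gene GADD45A rose by 2.16 ± 0.78 (adjusted p = 0.0338), the transcription factor IRF1 by 2.00 ± 0.92, the snoRNA host gene SNHG12 by 1.90 ± 0.53 and VPREB3 by 1.88 ± 0.96. LINCR (now NEURL3) rose by 2.59 ± 1.52, and the symbol P8, an older name of NUPR1 and of other genes, by 2.71 ± 0.81. The largest fall was in MAT2A, which makes S-adenosylmethionine, by 2.41 on the log2 scale (SD 1.18; adjusted p = 0.0386), although without both arrays numbered 3 its adjusted p was 0.153, at a larger difference of −2.75. LCMT2 fell by 2.14 ± 0.89, the ganglioside enzyme B4GALNT1 fell by 1.89 ± 0.30, cytochrome c (CYCS) fell by 1.72 ± 0.69 and RBM12 fell by 1.71 ± 0.30. ANKRD52 fell by 1.67 ± 0.64, C17ORF91 (now MIR22HG) fell by 1.66 ± 0.51, HSPA2 fell by 1.60 ± 0.67, GPRIN1 fell by 1.53 ± 0.20 and B3GALT6 fell by 1.50 ± 0.49. B4GALNT1, ANKRD52 and GPRIN1 were detected on 1 of 3 sorafenib arrays, CYCS and ANKRD37 on 2 of 3, and VPREB3 on 2 of 3 control arrays, so these sizes are set against signals near background. With the background estimated from all symbols, the size of 14 of the 34 genes named by the rule moved by over 1.5 times, and that of 20 did not. SNHG12 and VPREB3 were then at 0.27 each, IRF1 at 0.81 and P8 at 1.33. LCMT2 was at −0.33, B4GALNT1 at −0.14, CYCS at −0.14, RBM12 at −0.75, ANKRD52 at −0.11, C17ORF91 at −0.28, HSPA2 at −0.53, GPRIN1 at −0.08 and B3GALT6 at −0.73. PIM1 at 2.73, DDIT3 at 2.75, GADD45A at 2.55, LINCR at 2.46 and MAT2A at −2.61 moved less. Every gene named here as risen or fallen went the same way in all 3 pairs, which the rule itself asked of the largest changes. Over all genes, 3145 were higher and 3246 lower in all 3 pairs, where chance gives 1830 each on average. Genes are not independent, so such counts can lie far from that average by chance, and the excess was not tested. The 3 sorafenib arrays lay all above the 3 control arrays for 472 genes and all below for 476. Chance would give 732 each only if all 6 arrays were exchangeable. As arrays of the same number were alike, that value does not hold here and these counts cannot be called below chance.

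**Figure D4:**
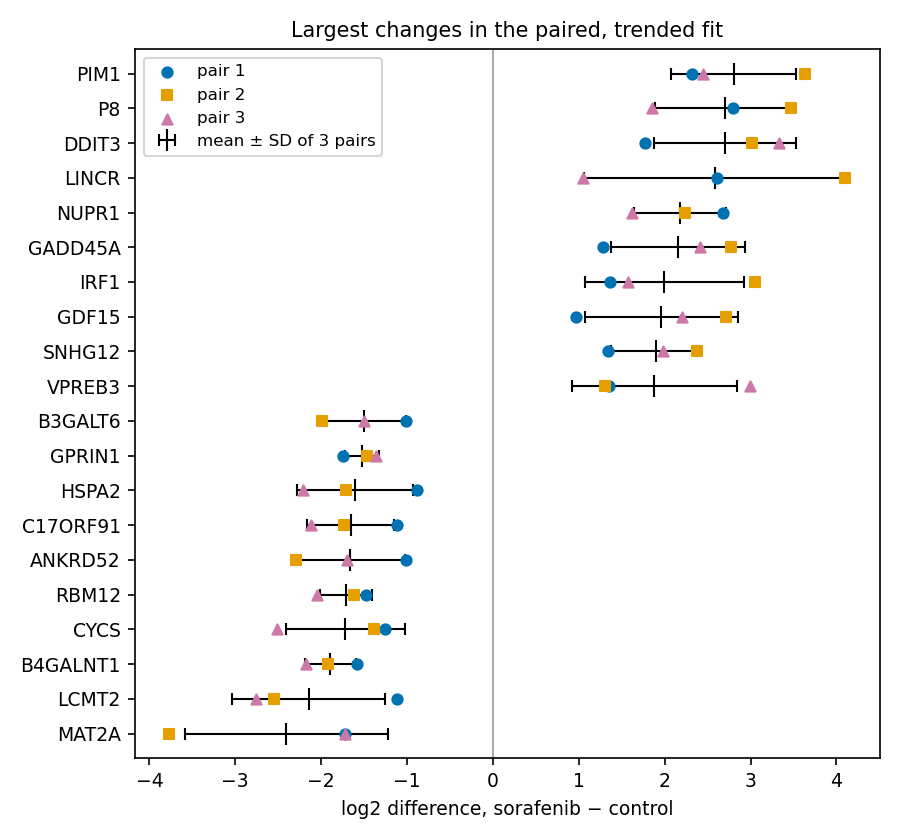
Log2 difference, sorafenib minus control, of the 10 genes with the largest rise and the 10 with the largest fall in the paired trended fit; symbols are the 3 pairs and bars their mean with SD. The mean of PIM1 is 2.80 and that of MAT2A is −2.41.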

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

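Of the tests below, those with the background estimated from all symbols, those without both arrays numbered 3, the set tests with the replicate block, and those of the paired trended fit and all its alternatives were chosen only after the result was seen. The other alternatives were planned. The main background estimate, from symbols that behaved as single probes, was itself chosen after the values were seen, and the estimate from all symbols is closer to the plan.

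In limma, the planned fit called 0 genes (310 at an unadjusted p under 0.05), and the count stayed at 0 under the other background corrections, offsets, scalings and filters, with array weights, with trend and robust estimation together, with the block alone and without any 1 array. It was 141 with the block, trend and robust estimation together and 320 with the block without both arrays numbered 3; at least 2-fold these were 106 and 320. Genes named by the rule beyond the PDI family numbered 0 in the planned fit and 36 and 44 in these fits, as distinct genes and with groups fully apart for the largest changes; asking for the same direction in every pair instead gave the 34 of the text. The paired trended count of 141 was 755 with array weights and 0 with the background estimated from all symbols, without the block, with neither trend nor robust estimation, and with robust estimation but no trend; with the trend but no robust estimation it was 123. It ranged from 1 to 1375 when a pair was left out. Its count at least 2-fold, 106, was 69 without background correction, 244 with array weights and 0 in the same 4 settings, with a range of 1 to 509 when a pair was left out. The cause of these moves was not tested.

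The number of lists past the threshold was 7 to 13 in the camera alternatives with a preset correlation, and 0 with an estimated correlation, with fry and with fry's mixed test, each without the block. With the block it was 0, 0 and 14. With an estimated correlation the adjusted p was 0.297 for ATF4 targets, 0.378 for MAPK/ERK output, glycolysis and fibroblast markers, 0.907 for G2/M, 0.361 for metallothioneins, 0.0954 for heat shock and cholesterol, 0.229 for fatty acid synthesis and 0.461 for autophagy. With fry it was 0.449 for ATF4 targets, 0.46 for MAPK/ERK output, metallothioneins and glycolysis, 0.985 for G2/M, 0.167 for heat shock, 0.182 for cholesterol, 0.152 for fatty acid synthesis and 0.709 for autophagy and fibroblast markers; fry's mixed test gave 0.888 for each. With the block, an estimated correlation gave 0.938 for G2/M and 0.84 for the other 9 lists, and fry gave 0.773 for G2/M, 0.107 for heat shock and fatty acid synthesis, 0.24 for cholesterol and 0.344 for the others. Its mixed test with the block gave 0.0811 for ATF4 targets, 0.0727 for MAPK/ERK output, 0.596 for G2/M, 0.18 for metallothioneins and 0.199 for fibroblast markers, and passed for fatty acid synthesis (4.97e-07), heat shock (0.00382), autophagy (0.0106), cholesterol (0.0216), glycolysis (0.0442), ER chaperones (0.0216) and 8 other lists. These tests allow for the correlation between genes or do not compare the list with other genes. Camera with an estimated correlation also rests on the few arrays, so lists lost there do not by themselves point to correlation.

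The ATF4, cholesterol and heat shock lists stayed past the threshold in 18, 19 and 19 of 24 alternatives, all but these set tests; the latter pair passed in the blocked mixed test. G2/M turned downward with array weights (0.455) and without both arrays numbered 3 (0.322, and 0.303 with the block). Glycolysis had 0.317 with array weights and 0.0563 without both arrays numbered 3, where it passed with the block (0.0438). Fibroblast markers had 0.0579 with median scaling, 0.239 without a detection filter, 0.0624 with trend and robust estimation, 0.175 with array weights and 0.0563 without both arrays numbered 3, where they passed with the block (0.0484). When 1 array was left out, the adjusted p ranged from 0.000317 to 0.178 for MAPK/ERK output, 6.4e-09 to 0.106 for G2/M, 0.00012 to 0.106 for metallothioneins, 0.00225 to 0.285 for glycolysis, 0.0023 to 0.0589 for fatty acid synthesis, 0.000459 to 0.514 for autophagy and 0.0167 to 0.663 for fibroblast markers. The fits without 1 array held no block, so an array without its partner brings differences between replicate numbers into the comparison. Whether this is the whole cause was not tested.

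Of 24 alternatives, the PDI family list passed in 0 and the ER chaperone list in 1, the blocked mixed test; the PDI median ranged from −0.26 to 0.07. No tested PDI member passed in any of 268 comparisons, and 10 of 15 members changed sign in at least 1. Any gene at all passed only in the paired trended fit and in the blocked fit without both arrays numbered 3. In the other settings the outcome was the same for every gene, so the count of comparisons is no evidence that PDI genes were stable. Of the 34 named genes of the paired trended fit none changed sign. This follows largely from their choice: they went the same way in every pair, so leaving out a pair cannot turn them. Changing the variance model leaves the differences as they are. In 279 comparisons the call was kept and in 197 it was lost, and 14 of the genes moved in size by over 1.5 times with the background estimated from all symbols. Among the other 20 lists, 18 changed sign somewhere, 3 of them under a scaling, and 31 comparisons passed the threshold. The fits on the deposited log2 table, on single probes and with a slide block, although planned, were not run. Signals near background limit what can be seen of dim genes.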

Other observations

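Of the tests below, the splits for the planned gene count and the lists were fixed before their results were seen. All other tests were chosen only after the result was seen. These concern the level-matched lists, the arrays numbered 3, ATF4 targets against ER chaperones, snoRNA host genes and the splits with the replicate block.

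Several genes outside the rule for named genes, chosen after their values were seen, also passed in the paired trended fit of limma. EGFR, the receptor of epidermal growth factor, rose by 1.32, and INHBE, an activin subunit gene made in liver, rose by 1.75. PPP1R15A, the phosphatase subunit that reverses eIF2alpha phosphorylation, rose by 1.61 ± 0.86, the amino acid transporter subunit SLC3A2 rose by 1.31, and CEBPG rose by 0.84 ± 0.24. The chaperones HSPA8 and HSP90AA1 fell by 0.90 and 0.83. The snoRNA host genes SNHG1 and TIGA1 rose by 1.65 and 1.44. With the background estimated from all symbols these calls end, as the count over all genes was 0, but the sizes did not shrink alike: INHBE was then at 2.22, PPP1R15A at 1.94, SLC3A2 at 1.65, CEBPG at 1.04, HSPA8 at −1.02, HSP90AA1 at −1.04, SNHG1 at 1.79 and TIGA1 at 1.82, each farther from 0, and EGFR was at 1.13. Of 30 hepatocyte secreted genes, 17 were lower and 5 higher on both arrays numbered 3 than on each of the other 4, with a median difference of −2.63 (AFP 6.49 against 12.37, but ALB 14.24 against 9.44).

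Both arrays numbered 3 differed from the other 4 in which genes were expressed; dimmer hybridization is argued against by 95 symbols that were detected there alone and brighter by more than 4 log2. RNA of other cells added to the same cells is argued against by 14 of 509 bright symbols that were lower there by more than 4 log2, a loss that added RNA cannot give while at least 1 part in 16 of the RNA is from the same cells. Both samples numbered 3 shared the difference, as a difference of the cells would give, though the origin remains open. Of 469 symbols that differed by more than 4 log2 among controls, 78.3% did so in the same direction among sorafenib arrays. For arrays numbered 1 and 2 the shares were 73.7% of 38 symbols and 61.5% of 26. There each array was set against the mean of the other arrays of its group, which held the array numbered 3. A symbol such as GPC3, at 14.13, 14.02 and 4.84 on controls 1 to 3, can therefore be counted although arrays 1 and 2 agree. These shares cannot serve as a comparison for the arrays numbered 3. The difference of the cells may be another line, a mislabelled culture or drift, which was not tested.

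The list shifts could in principle follow signal level. Quantile normalization removes part of such a trend. The median differences of 20 level bins ran from −0.05 to 0.03 with it and from −0.11 to 0.04 with median scaling. The trend was therefore tested on median-scaled values. There, random lists matched for level had expected shifts of at most 21.4% of a list's median, reached by autophagy and of the opposite sign (−0.04 against 0.19), and of at most 10.2% for the other 9 lists, which argues against level as the whole cause. The correlation between genes of a list stays open as a reason for low p-values. With an estimated correlation 0 of the 10 lists passed, but this cannot decide the question. That setting also rests on the few arrays rather than on the many genes, which by itself raises p-values. Without the block, its estimate also takes in the differences between replicate numbers, which held 88.1% of the sum of squares.

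Of the 10 splits of the 6 samples, 1, the real one, gave as many as 10 lists, and the highest other gave 8; the splits are too few for a share under 0.05. For the planned gene count, 10 of 10 splits gave as many, the real value and the highest other both being 0 in limma with 310 genes at an unadjusted p under 0.05 in the real split, and again the splits are too few. For the paired trended fit, 1 of the 4 splits that part every pair gave as many genes, the real one with 141, and the highest other gave 0. In the same splits, camera with the preset correlation and the block passed 11 lists for the real one. It passed 8, 6 and 9 lists for the others, so wrong groupings passed nearly as many. Again, 4 splits are too few for a share under 0.05. Splits that kept both arrays numbered 3 together gave 1547 to 3104 genes at an unadjusted p under 0.05, several times the 310 of the real split, which points to a structure of the samples.

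ATF4 targets rose in camera with a preset correlation (adjusted p = 0.297 with an estimated correlation), while ER chaperones did not pass. The ATF4 median exceeded the ER chaperone median by 0.61 (SD 0.46 over pairs; 0.24, 0.41 and 1.11). Whether ATF4 may act here without induction of ER chaperones stays open, since both lists, though fixed before the values were seen, were set against each other because of this very difference, and the comparison only restates it. With 3 pairs the smallest exact two-sided p is 0.25.

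A hypothesis is that RNAs removed by translation-dependent decay, such as host genes of small nucleolar RNAs, may rise together, as SNHG12 did, though SNHG12 itself was at 0.27 with the background estimated from all symbols. The 10 other noncoding host genes had a median of 0.71 (pair medians 0.40, 0.95 and 1.03), 6 were higher and 0 lower in all pairs, and 2 were called over all genes in the paired trended fit. Camera with a preset correlation gave a p of 1.24e-05 (not adjusted, 1 list), but an estimated correlation gave a p of 0.112, so the shift is not established. With the background estimated from all symbols their median was 0.60, and camera gave 2.32e-05. A rise in their transcription stays open, as translation and decay were not measured.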
